A study of Mus musculus with 78 samples.

How the data were processed

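Kidney RNA was measured in male C57BL/6J mice, an inbred laboratory strain, after 8 weeks on 1 of 3 diets. The diets were a low-fat diet with 4% fat (LFD), a high-fat diet with 31% fat (HFD) and a diet deficient in methionine, choline and folate (MCD). Mice received tetrachloroethylene (PERC), a solvent used in dry cleaning and metal degreasing, at 300 mg/kg per day, or the vehicle. Per the series description, a single PERC dose was followed by death at 24 h, and 5 daily doses of PERC or vehicle were followed by death at 4 h after the last dose. The time of death of the single-regimen vehicle mice was not given in the sources used here, so the single-regimen comparisons may set unequal times side by side. Total RNA came from pulverized kidney, and libraries were made with a stranded kit for messenger RNA, per the labels' protocols.

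The deposited values are whole-number read counts per gene symbol, 1 file per library, with no normalization by the authors. Per the submitters' processing notes, bcl2fastq 2.17.1.14, Trimmomatic, TopHat2 2.0.13, HTSeq and DESeq2 were used with the mouse build GRCm38 (mm10). The notes give these names with no role or order. The gene annotation and the strand setting of the counting were not given in the sources used here, so values of genes that overlap another gene, on either strand, are uncertain. Reads that the counter assigned to no gene stayed out of library sizes and tests. Over the 72 libraries used, the deposited counts put 53.1% of reads in genes (median, range 45.4% to 62.3%), 22.9% in no feature, 21.7% aligned to several places, 2.28% not aligned and 0.686% ambiguous. The 10 most abundant genes took 6.96% to 10.2% of the counts in genes. Because reads aligned to several places were not counted in genes, members of gene families with near-identical copies are uncertain: the Cyp4a genes, Acot1, Aldh1a1 and Aldh1a7, the Ugt1a genes, and Gsta1 with its predicted copy Gm3776.

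The labels name 78 samples in 12 groups of diet, regimen and treatment. Of these, 77 had a file, and 1 library of the MCD repeated vehicle group was not analysed here. Replicate numbers were given in accession order and only name a library. A minimum of 1000000 counts in genes per library left out 5 single-regimen libraries that held 2267 to 22029 counts: LFD PERC replicate 2, HFD vehicle replicate 2, MCD PERC replicate 2 and MCD vehicle replicates 1 and 4. The 72 libraries used held 9047579 to 42022166 counts in the single regimen (25 libraries, sequencing lanes 1 to 3) and 8556278 to 28508827 in the repeated regimen (47 libraries, lanes 4 to 8). The lane was read from the file names. Labels put 9 libraries in the LFD repeated PERC group and 7 in its vehicle group, where the series description gives 8 for each. The labels do not say that each library came from another animal, although the description counts mice per group, so p-values measure the spread between libraries. Within groups, 203 pairs of libraries were compared over genes with at least 20 counts. None was identical (lowest chi-square per gene 6.38), which does not show that they came from different animals, and every library was taken as 1 replicate.

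Of 24499 genes in the files, filterByExpr kept 14280 in the single regimen, 14614 in the repeated regimen and 15139 over all libraries. Counts were scaled with TMM factors, which ran from 0.948 to 1.06 in the single and from 0.932 to 1.06 in the repeated regimen. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust dispersion) with 1 mean per group. Each regimen was fitted over its 6 groups, since the regimens share no lane, and regimens were compared in 1 fit over the 12 groups. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors (SE) are the size of the log2 fold change divided by the square root of F in the same tests. Levels are CPM (counts scaled to a library of 1000000 counts), and log2 CPM values used a prior count of 2. The common biological coefficient of variation was 0.191 in the single and 0.157 in the repeated regimen.

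There were 17 comparisons. PERC was set against vehicle within each diet and regimen. Vehicle libraries on the HFD and MCD diets were set against LFD vehicle libraries within each regimen. The PERC effect in HFD and in MCD mice was compared with that in LFD mice, and the PERC effect of the repeated regimen with that of the single regimen. These comparisons, the settings and 38 gene lists (21 of pathways and 17 of cell types) were fixed before the data were examined. Lists with at least 5 tested members were tested against all other genes with camera (limma 3.58.1, log2 CPM, preset correlation between genes 0.01), adjusted over the lists of a comparison, and again with a correlation estimated from the data. Counts of list members called "adjusted over the list alone" used the Benjamini-Hochberg adjustment within that list.

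The rule for genes named in the text was also fixed. It takes, for PERC and diet comparisons, the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 1 and an established symbol. It adds up to 4 members of each list with the smallest p, and 10 genes in every comparison, among them Havcr1, Lcn2, Cyp4a10, Cyp4a14, Acot1, Cyp2e1, Kyat1 and Cdkn1a; the other 2 are not reported here. For differences between diets or regimens it takes the 10 called genes with the smallest p, or the 3 smallest if none was called. Gene positions are from GENCODE M21 on GRCm38, where 23638 of the symbols were found once.

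The fits were tested on simulated counts drawn from the real means and library sizes, with 200 genes changed by known folds. For PERC in LFD mice of the single regimen (14163 genes), 77.6% of 2-fold changes and 95.9% of 4-fold changes were recovered. In the repeated regimen (14545 genes) these shares were 91.8% and 100%. For the difference between the HFD and LFD effects of a single dose (14174 genes), 54.0% of 2-fold and 90.0% of 4-fold differences were recovered. Between 1.17% and 7.54% of calls in these simulations were false. The simulated counts held no lane effect and no correlation between genes, so these shares may not hold for the real data.

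Alternatives were DESeq2 1.42.0, RLE factors in place of TMM, no filter on low counts, lane as a covariate, libraries of low depth kept in, a minimum of 5000000 counts, only the groups compared in the fit, and each library of the single regimen and of LFD repeated mice left out in turn. Fits with lane or with DESeq2 without 1 doubted library, fits of PERC in HFD and MCD repeated mice without 1 of 3 libraries far from their group, and fits with the mean level of adipocyte and brown adipocyte markers as a covariate, were added after the data were seen. Comparisons of MCD with HFD mice were not used here.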

Results

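Messenger RNA was sequenced from kidneys of male C57BL/6J mice on 3 diets that were given the solvent PERC or its vehicle. The title of the series asks whether fatty liver, modelled by the HFD, and steatohepatitis, modelled by the MCD diet, alter the effects of PERC on the kidney. After a single dose, the libraries used were 4 PERC and 5 vehicle on LFD, 5 PERC and 4 vehicle on HFD, and 4 PERC and 3 vehicle on MCD. After 5 daily doses they were 9 and 7 on LFD, 8 and 8 on HFD, and 8 and 7 on MCD. Counts in genes ran from 9047579 to 42022166 per library in the single regimen and from 8556278 to 28508827 in the repeated regimen. In the single regimen, the first principal component (33.1% of variance) followed sequencing lane (r2 = 0.753), and the second (10.2%) followed diet (r2 = 0.802). In the repeated regimen, the first component (19.5%) went most with lane (r2 = 0.374), the second (17.7%) followed treatment (r2 = 0.504), and the third (8.53%) followed diet (r2 = 0.843).

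Does a single dose of PERC change kidney expression in LFD mice? At 24 h after the dose, genes of fatty acid oxidation led the increases in 4 PERC against 5 vehicle libraries. Cyp4a14, a fatty acid omega-hydroxylase gene (chromosome 4, 115486200 to 115496142, GRCm38), rose 54.8-fold (log2 fold change 5.78, SE 0.91, edgeR adjusted p = 0.00245). Its level was 28.1 ± 25 CPM (SD, n = 5) with vehicle and 1530 ± 1434 CPM (n = 4) with PERC. Cyp4a10 rose by a log2 value of 2.70 (SE 0.34, adjusted p = 0.000356). The aldehyde dehydrogenase genes Aldh1a1 and Aldh1a7, which share sequence, rose by 1.92 and 1.89 (SE 0.26 each). The injury marker Havcr1, which codes for kidney injury molecule 1, did not pass the test (log2 1.73, SE 0.58, adjusted p = 0.241), nor did Lcn2 (1.43, SE 0.44, adjusted p = 0.166). Cdkn1a, a member of the tubular injury and p53 lists, rose by 0.91 (SE 0.19, edgeR adjusted p = 0.0193). It did not pass in HFD (0.014, SE 0.20) or MCD mice (0.090, SE 0.22) after a single dose.

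Of 43 measured targets of the lipid-sensing receptor PPARA and fatty acid oxidation genes, 23 rose, 0 fell and 20 did not pass in LFD mice after a single dose (35 rose when adjusted over the list alone, and 15 over all genes with the level of adipocyte markers as a covariate). The list as a whole lay higher (median log2 0.847, camera adjusted p = 7.79e-46, and adjusted p = 0.0266 with an estimated correlation). With the adipocyte markers as a covariate, the median of the list was 0.692. Among its members, Acot1 rose by 2.10 (SE 0.31) and Eci1 by 1.17 (SE 0.18). Of 29 genes of the amino acid response driven by ATF4, 3 rose (10 adjusted over the list alone), among them the asparagine synthetase gene Asns (1.92, SE 0.27, adjusted p = 0.000641) and the mitochondrial folate enzyme gene Mthfd2 (1.85, SE 0.26). That list passed with both correlations (median 0.406, adjusted p = 4.74e-14, and adjusted p = 0.00851 with an estimated correlation). Of 22 NRF2 targets, a list of oxidative stress genes, 2 rose, Nqo1 (0.70, SE 0.14) and the transporter gene Abcc4 (0.65, SE 0.11), and 7 rose and 1 fell when adjusted over the list alone (median 0.143, adjusted p = 0.000158, and adjusted p = 0.0266 with an estimated correlation). Of 31 genes of glutathione conjugation and mercapturate formation, the route by which PERC is known to form kidney toxicants, 2 rose (Mgst1 and Gstt2) and Acy3, an aminoacylase gene, fell (camera adjusted p = 0.00369, and adjusted p = 0.349 with an estimated correlation). Among 9 male-enriched kidney genes only the transporter gene Slc7a13 fell (log2 -0.97, SE 0.19), while 6 fell and 1 rose when adjusted over the list alone (adjusted p = 1.10e-05, and adjusted p = 0.148 with an estimated correlation). None of 11 adipocyte markers passed, with a median log2 value of 1.41 (camera adjusted p = 0.00127, and adjusted p = 0.424 with an estimated correlation).

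In all, 107 of 14280 genes were called in LFD mice after a single dose (76 higher, 31 lower; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). With DESeq2, 222 were called (57.2% of them higher), and with lane as a covariate 286 (47.6% higher), while a fit to only these groups called 8 and one with the adipocyte covariate 49. The count was 19 without PERC replicate 4, 44 without PERC replicate 1, 62 and 67 without vehicle replicates 5 and 2, 232 without PERC replicate 5 and 285 without PERC replicate 3. Of 32 named genes called, 11 kept the call whichever library was left out, among them Cyp4a14, Cyp4a10, Acot1, Eci1, Asns, Mthfd2, Aldh1a1, Aldh1a7, Abcc4 and Ugt1a10. Those of Nqo1, Mgst1, Gstt2, Acy3 and Slc7a13 did not, with highest adjusted p of 0.136, 0.0706, 0.328, 0.210 and 0.127.

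In HFD mice, a single dose gave 1 called gene, Aldh1a7, which rose by a log2 value of 1.83 (SE 0.27, edgeR adjusted p = 0.0124; 5 PERC against 4 vehicle libraries), from 12.2 ± 6.04 to 42.9 ± 12.4 CPM. Cyp4a10 (1.55, SE 0.34, adjusted p = 0.219) and Cyp4a14 (2.11, SE 0.82, adjusted p = 1) did not pass. Vehicle levels of Cyp4a14 ran from 17.5 to 347 CPM in the 4 HFD vehicle libraries. None of 43 PPARA and fatty acid oxidation genes passed over all genes, and 23 rose when adjusted over the list alone (median 0.430, camera adjusted p = 1.14e-36, and adjusted p = 0.106 with an estimated correlation). The 35 cell cycle genes had a median of -0.408, with 0 called over all genes and 4 lower when adjusted over the list alone (adjusted p = 1.91e-09, and adjusted p = 0.106 with an estimated correlation). DESeq2 called 13 genes (7 higher, 6 lower), 577 genes had an unadjusted p under 0.05, and 2 were called with the libraries of low depth kept in. If no gene differed, a share of 0.05 of the 14280 tested genes would be expected under that p, which is more than 577. A fit to only these groups lost Aldh1a7 and called 1 other gene. The count was 3 without vehicle replicate 1 (1 higher, 2 lower) or 4, and 0 without PERC replicate 1 or vehicle replicates 3 or 5.

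In MCD mice, 4 genes rose after a single dose (4 PERC against 3 vehicle libraries). They were Cyp4a10 (log2 2.47, SE 0.40, edgeR adjusted p = 0.0256), Aldh1a7 (2.04, SE 0.32, adjusted p = 0.0228), Cyp4a31 (1.68, SE 0.30, adjusted p = 0.0491) and the beta-oxidation thiolase gene Acaa2 (0.96, SE 0.18, adjusted p = 0.0491). Cyp4a14 (5.32, SE 1.12, adjusted p = 0.127) did not pass, nor did Asns and Mthfd2 (1.71 and 1.58, adjusted p = 0.0556 each) or Havcr1 (0.70, SE 0.70). Of the 43 PPARA and fatty acid oxidation genes, 3 rose over all genes, and 28 rose and 1 fell when adjusted over the list alone (median 0.71, camera adjusted p = 6.50e-40, and adjusted p = 0.0482 with an estimated correlation). The ATF4 list had a median of 0.238, with 0 members called over all genes and 8 higher when adjusted over the list alone (adjusted p = 1.17e-09, and adjusted p = 0.0482 with an estimated correlation). DESeq2 called 38 genes higher and 5 lower, lane as a covariate gave 17 calls, and keeping the libraries of low depth gave 13. None was called without PERC replicate 1 or vehicle replicates 2 or 5, and 2 without PERC replicate 3 or 5. Without vehicle replicate 3, none of the 4 passed and 1 other gene was lower.

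The direct test of whether the single-dose effect differed from that in LFD mice called 0 genes for HFD and 0 for MCD with edgeR. At an unadjusted p under 0.05 there were 791 and 600 genes, DESeq2 called 3 and 2, and lane as a covariate gave 1 and 1. If no gene differed, a share of 0.05 of the 14280 tested genes would be expected under that p, more than 600 and fewer than 791. The smallest p values belonged to the epithelial transcription factor gene Ehf for both diets (log2 difference -1.17, SE 0.24, adjusted p = 0.374 for HFD; -1.37, SE 0.26, adjusted p = 0.331 for MCD). Cyp4a14 (-3.67, SE 1.11, adjusted p = 0.699) did not pass for HFD. The PPARA and fatty acid oxidation list had a median difference of -0.348 for HFD (camera adjusted p = 2.17e-05, and adjusted p = 0.638 with an estimated correlation). The glucocorticoid response list, made of genes such as Fkbp5 and Zbtb16, had a median of -0.826 for HFD (adjusted p = 2.28e-06, and adjusted p = 0.173 with an estimated correlation) and -0.784 for MCD (adjusted p = 0.000143, and adjusted p = 0.491 with an estimated correlation), with 0 members called over all genes, and 6 and 3 lower when adjusted over the list alone. The count for HFD became 3 without LFD PERC replicate 3 and 1 without LFD PERC replicate 5, and the count for MCD became 2 without LFD PERC replicate 3.

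**Figure D1:**
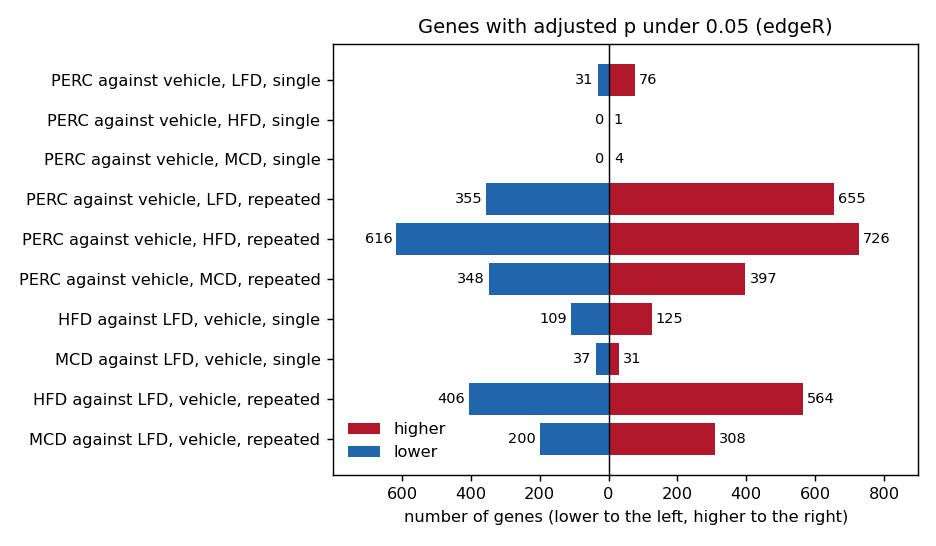
Numbers of genes called higher (bars to the right) and lower (bars to the left) in each comparison, in genes at an adjusted p under 0.05 (edgeR). For PERC, 107, 1 and 4 genes were called in LFD, HFD and MCD mice after a single dose, and 1010, 1342 and 745 after 5 doses. After 5 doses, 1798 were called in LFD mice without PERC replicate 4, and 928 in HFD mice without PERC replicate 6. The counts therefore do not rank the diets. Direct tests of the difference from LFD called 0 genes for HFD and 0 for MCD after a single dose, and 2 and 0 after 5 doses.

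After 5 daily doses, the injury marker Havcr1 and the fatty acid hydroxylase gene Cyp4a14 were among the genes that rose in LFD mice (9 PERC against 7 vehicle libraries). Havcr1 (chromosome 11, 46735080 to 46779578) rose 27.4-fold (log2 4.78, SE 0.69, edgeR adjusted p = 1.24e-05), from 2.30 ± 0.389 to 63.5 ± 62.9 CPM, and Cyp4a14 rose by a log2 value of 5.00 (SE 0.57, adjusted p = 1.53e-07). Gc, the gene of the vitamin D binding protein (chromosome 5, 89417522 to 89457898), rose from 58.3 ± 10 to 793 ± 455 CPM (log2 3.77, SE 0.37, adjusted p = 7.86e-09). The glutathione transferase gene Gsta1 rose by 5.42 (SE 0.79), the pseudokinase gene Trib3 by 3.60 (SE 0.51) and Asns by 3.03 (SE 0.34). The cell cycle inhibitor gene Cdkn1a rose by 1.49 (SE 0.34, adjusted p = 0.00405), and Lcn2 did not pass (0.98, SE 0.48, adjusted p = 0.234). Among the decreases were the carboxylesterase gene Ces1g (-1.76, SE 0.40) and the DNA topoisomerase gene Top2a (-1.25, SE 0.24).

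Of 43 PPARA and fatty acid oxidation genes, 29 rose, 1 fell and 13 did not pass in LFD mice after 5 doses (31 rose and 2 fell when adjusted over the list alone; camera adjusted p = 6.59e-22, and adjusted p = 0.0964 with an estimated correlation). These included Fabp1, a fatty acid binding protein gene (2.67, SE 0.43). Of 31 ATF4 genes, 18 rose and 0 fell (22 adjusted over the list alone; adjusted p = 1.10e-22, and adjusted p = 0.0616 with an estimated correlation). These included Mthfd2 (2.12, SE 0.28) and Atf5 (2.37, SE 0.34). Of 24 NRF2 targets 13 rose and 1 fell (14 and 2 adjusted over the list alone; adjusted p = 4.03e-06, and adjusted p = 0.132 with an estimated correlation), and the carbonyl reductase gene Cbr3 rose by 3.12 (SE 0.56). Of 27 tubular injury and repair genes 7 rose (8 adjusted over the list alone; adjusted p = 0.000725, and adjusted p = 0.148 with an estimated correlation). These included Krt20 (3.25, SE 0.70) and the growth factor gene Areg (4.41, SE 0.92). Of 25 p53 targets 7 rose (11 rose and 1 fell adjusted over the list alone; adjusted p = 0.000118, and adjusted p = 0.0616 with an estimated correlation). Of 36 cell cycle genes 8 fell (15 fell and 1 rose adjusted over the list alone; adjusted p = 4.03e-06, and adjusted p = 0.176 with an estimated correlation). These included Mki67 (-1.0, SE 0.27) and Ccnb2 (-1.05, SE 0.25). Of 26 cholesterol synthesis genes 9 rose (12 rose and 1 fell adjusted over the list alone; adjusted p = 2.73e-05, and adjusted p = 0.243 with an estimated correlation). These included Insig1 (1.10, SE 0.17) and Fdps (0.93, SE 0.16). Adipocyte markers moved with these groups: 7 of 11 rose (10 adjusted over the list alone; median 2.02, adjusted p = 1.29e-09, and adjusted p = 0.0964 with an estimated correlation), with Adipoq, the adiponectin gene, at 2.42 (SE 0.57). With the level of adipocyte markers as a covariate, 21 of the 43 PPARA and fatty acid oxidation genes rose. The median log2 value of the 43 genes was 0.446 with the covariate and 0.475 without it.

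The test called 1010 of 14614 genes in LFD mice after 5 doses (655 higher, 355 lower). The library labelled LFD repeated PERC replicate 4 lay with the vehicle libraries for PERC-responsive genes, at 121 CPM of Cyp4a14 and 1.82 CPM of Havcr1. Without it, 1798 genes were called and the values above were 4.94 for Havcr1, 5.16 for Cyp4a14 and 3.93 for Gc. In that fit, the ATF4 and p53 lists passed with both correlations (adjusted p = 0.0306 each with an estimated correlation). Without PERC replicate 1 or 8 the count was 640 or 645, without vehicle replicate 7 it was 650, and a fit to only these 2 groups called 363, and one with the adipocyte covariate 669. The calls of Ccnb2 and Mki67 were each lost without 1 or more of the 16 libraries (highest adjusted p = 0.0602 and 0.0593), and those of the other genes named for LFD mice after 5 doses were kept.

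**Figure D2:**
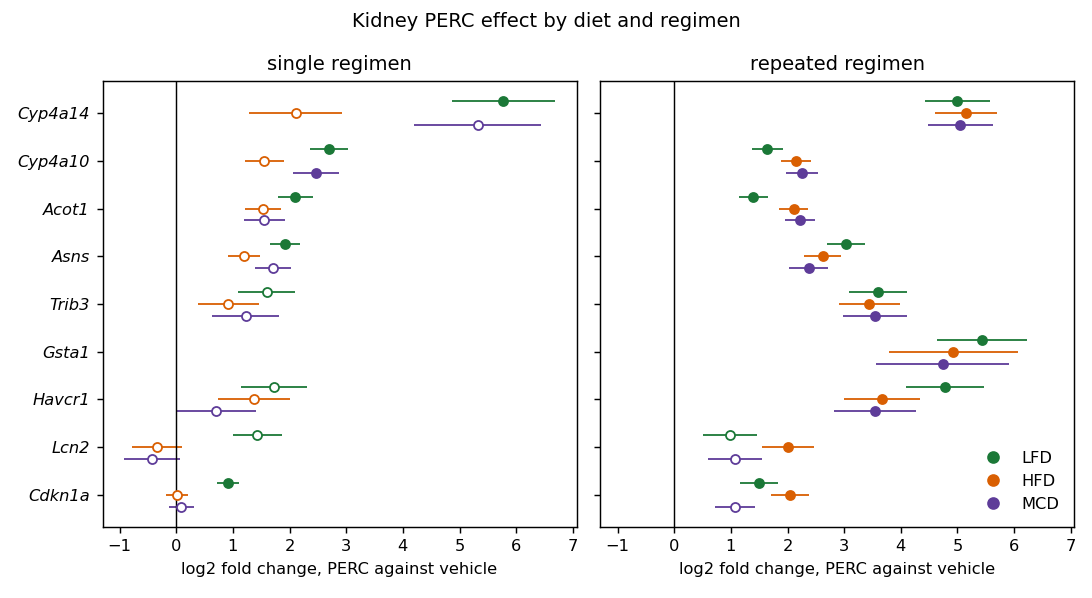
Log2 fold changes of PERC against vehicle for selected genes in each diet and regimen; points are estimates, filled where the adjusted p was under 0.05, and bars are 1 SE. Havcr1 rose in all 3 diets after 5 doses (4.78, 3.67 and 3.54 in LFD, HFD and MCD mice) and passed in none after a single dose. Gsta1 had too few counts to be tested in the single regimen.

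In HFD mice, 5 doses of PERC raised Cyp4a14 by a log2 value of 5.15 (SE 0.55, edgeR adjusted p = 1.77e-08) and Gc by 4.11 (SE 0.36, adjusted p = 2.34e-10), in 8 PERC against 8 vehicle libraries. Havcr1 rose by 3.67 (SE 0.67, adjusted p = 0.000183), from 1.97 ± 0.916 CPM (range 1.21 to 3.95) to 25.2 ± 33.5 CPM (range 6.56 to 106). Lcn2, the injury marker lipocalin-2, rose by 2.0 (SE 0.46, adjusted p = 0.00288). That call rested on PERC replicate 6, without which the value was 1.06 (SE 0.36, adjusted p = 0.0695). Cdkn1a rose by 2.05 (SE 0.34, adjusted p = 3.73e-05). Pdk4, a kinase gene that restrains glucose oxidation, rose by 3.56 (SE 0.41) and Fabp1 by 3.63 (SE 0.46). The organic anion transporter gene Slc22a7 fell by 2.32 on the log2 scale (SE 0.62), and the deiodinase gene Dio1 by 1.37 (SE 0.27).

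Of the 43 PPARA and fatty acid oxidation genes, 34 rose in HFD mice after 5 doses, 0 fell and 9 did not pass (37 rose adjusted over the list alone; median 0.807, camera adjusted p = 5.45e-49, and adjusted p = 0.00373 with an estimated correlation). Examples are Ucp2 (1.87, SE 0.19), Angptl4, an inhibitor of lipoprotein lipase (1.87, SE 0.21), and Acadvl (0.56, SE 0.06). Of 27 tubular injury and repair genes, 11 rose (14 adjusted over the list alone; adjusted p = 1.46e-07, and adjusted p = 0.0163 with an estimated correlation). These included the fibrinogen gene Fga (1.39, SE 0.22). Of 31 ATF4 genes, 19 rose (27 adjusted over the list alone; adjusted p = 5.58e-24, and adjusted p = 0.0163 with an estimated correlation). These included Asns (2.62, SE 0.33) and Psat1 (1.07, SE 0.15). Of 25 p53 targets, 7 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 2.54e-07, and adjusted p = 0.00373 with an estimated correlation). Of 22 inflammatory and acute phase genes, 6 rose (9 rose and 1 fell adjusted over the list alone; adjusted p = 0.000102, and adjusted p = 0.0408 with an estimated correlation). These included the oncostatin M receptor gene Osmr (1.05, SE 0.17) and Socs3 (1.23, SE 0.24). Clock genes went both ways: of 19, 4 rose and 5 fell (5 and 7 adjusted over the list alone), with Npas2 at 1.73 (SE 0.24) and Dbp at -1.25 (SE 0.23). Of 14 glucocorticoid response genes 5 rose (9 adjusted over the list alone; adjusted p = 1.74e-05, and adjusted p = 0.277 with an estimated correlation), and of 24 NRF2 targets 6 rose (8 adjusted over the list alone; adjusted p = 0.00234, and adjusted p = 0.411 with an estimated correlation). Of 11 adipocyte markers, 3 rose (adjusted p = 0.0326, and adjusted p = 0.629 with an estimated correlation), and 34 PPARA and fatty acid oxidation genes rose with those markers as a covariate. In all, 1342 genes were called, 726 higher and 616 lower, and 928 were called without PERC replicate 6. The list tests were not rerun without that library. Lcn2, whose call rested on it, is a member of the tubular injury, inflammatory and glucocorticoid lists.

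In MCD mice, 5 doses raised Cyp4a14 by a log2 value of 5.05 (SE 0.58, edgeR adjusted p = 1.65e-07), Gc by 4.21 (SE 0.39, adjusted p = 7.07e-10) and Havcr1 by 3.54 (SE 0.72, adjusted p = 0.00126), in 8 PERC against 7 vehicle libraries. Havcr1 stood at 1.48 ± 0.184 CPM with vehicle and 17.1 ± 13.9 CPM with PERC. Chac1, an enzyme gene of glutathione breakdown under ATF4 control, rose by 3.11 (SE 0.48), Fabp1 by 3.73 (SE 0.46) and Pdk4 by 3.39 (SE 0.43). Slc22a7 (log2 -3.14, SE 0.66, adjusted p = 0.00183) and Ces1g (-2.21, SE 0.46) fell, while Cdkn1a (1.08, SE 0.35, adjusted p = 0.0639) and Lcn2 (1.07, SE 0.48, adjusted p = 0.222) did not pass. Of the 43 PPARA and fatty acid oxidation genes, 32 rose, 0 fell and 11 did not pass (36 rose and 2 fell adjusted over the list alone; median 0.691, camera adjusted p = 1.70e-55, and adjusted p = 0.00253 with an estimated correlation). Of 31 ATF4 genes, 16 rose (21 adjusted over the list alone; adjusted p = 3.72e-18, and adjusted p = 0.0720 with an estimated correlation), and of 27 tubular injury and repair genes 6 rose (10 rose and 2 fell adjusted over the list alone; adjusted p = 0.00231, and adjusted p = 0.272 with an estimated correlation). Of 28 interferon response genes, 7 fell (15 adjusted over the list alone; median -0.310, adjusted p = 2.98e-10, and adjusted p = 0.0629 with an estimated correlation). These included the antiviral genes Mx1 (-0.81, SE 0.20), Oasl2 (-0.36, SE 0.09) and Igtp (-0.51, SE 0.12). Of 15 macrophage and dendritic cell markers, 3 fell (7 adjusted over the list alone; median -0.354, adjusted p = 1.47e-06, and adjusted p = 0.173 with an estimated correlation): Csf1r (-0.58, SE 0.11), H2-Aa (-0.36, SE 0.11) and H2-Ab1 (-0.51, SE 0.16), the last with an adjusted p of 0.0559 with lane as a covariate. In all, 745 genes were called, 397 higher and 348 lower, and with lane as a covariate 364 and 369.

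The 3 repeated-regimen comparisons share no library, but they share 1 fit, its estimates of spread per gene, and the lanes. The overlaps of independent lists are therefore only a rough guide to chance. LFD and HFD mice shared 320 higher and 155 lower genes, where independent lists would share 32.5 and 15, and HFD and MCD mice shared 322 and 232 against 19.7 and 14.7. LFD and MCD mice shared 216 and 90, against 17.8 and 8.45. No gene was called in opposite directions in any of these pairs. Of the 107 genes called in LFD mice after a single dose, 107 had the same sign in LFD mice after 5 doses, and 61 higher and 16 lower genes were called in both (3.40 and 0.767 by chance).

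**Figure D3:**
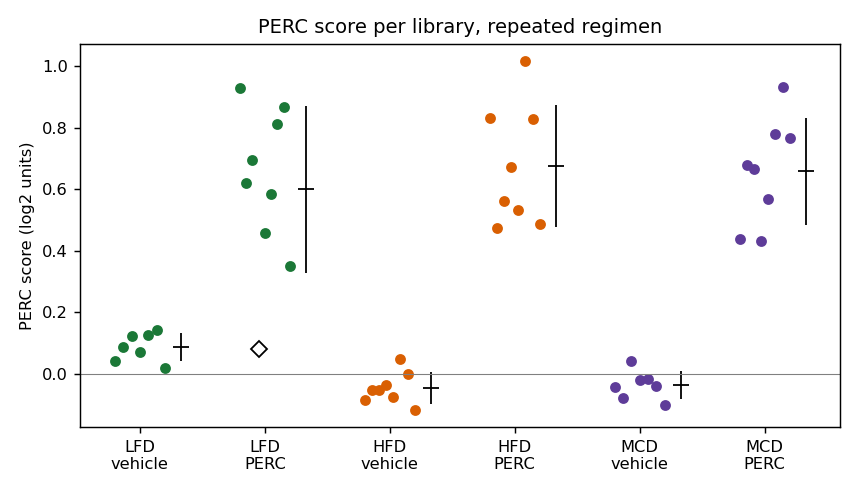
PERC score of each repeated-regimen library: the mean over 554 genes, called in both HFD and MCD mice, of the log2 CPM deviation from the mean of all vehicle libraries, signed by direction. Points are libraries, bars are mean and SD, and the diamond is the library labelled LFD repeated PERC replicate 4, at 0.0827; the other 8 LFD PERC libraries lay between 0.350 and 0.928.

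Whether 5 doses act differently in HFD than in LFD mice was tested directly. Angptl4 (chromosome 17, 33773750 to 33781830) responded more in HFD mice: it rose from 47.8 ± 11.6 to 174 ± 63.1 CPM there, and stood at 87.4 ± 21.7 CPM with vehicle and 111 ± 29.7 CPM with PERC in LFD mice (log2 difference 1.53, SE 0.28, edgeR adjusted p = 0.0176). With the level of adipocyte markers as a covariate the call was lost: the difference was 1.54, with a wider SE of 0.30 (adjusted p = 0.0599). The other called gene was Sntg2, a syntrophin gene chosen after its values were seen because its mean log2 CPM was 0.40 (difference 1.54, SE 0.27, adjusted p = 0.0122). Havcr1 did not pass for HFD (-1.11, SE 0.94, adjusted p = 0.944) or for MCD (-1.23, SE 0.99, adjusted p = 0.988), and Pdk4 did not for HFD (2.03, SE 0.53, adjusted p = 0.325). For MCD against LFD, 0 genes were called with edgeR, 944 had an unadjusted p under 0.05, DESeq2 called 2, lane as a covariate gave 3 and RLE scaling gave 1. If no gene differed, a share of 0.05 of the 14614 tested genes would be expected under that p, which is fewer than 944. The smallest p values for MCD against LFD belonged to Banp (1.41, SE 0.27, adjusted p = 0.0514) and Zfp493 (0.85, SE 0.18, adjusted p = 0.120). The PPARA and fatty acid oxidation list had a median difference of 0.215 for HFD (camera adjusted p = 1.74e-14, and adjusted p = 0.801 with an estimated correlation) and 0.233 for MCD (adjusted p = 5.89e-13, and adjusted p = 0.691 with an estimated correlation). Adipocyte markers had median differences of -1.53 (adjusted p = 0.000141, and adjusted p = 0.801 with an estimated correlation) and -1.83 (adjusted p = 6.09e-06, and adjusted p = 0.691 with an estimated correlation). DESeq2 called 6 genes for HFD (4 higher, 2 lower), and the adipocyte covariate left 1, which was not Angptl4. Chance was not excluded for the 2 calls, since 6 of 100 splits of the libraries gave at least as many. Without LFD PERC replicates 1, 3 or 4 the HFD count was 4, 5 or 4; for MCD it was 3 without LFD PERC replicate 4 and 1 without LFD vehicle replicate 3 or 4. Without LFD PERC replicate 4, lane as a covariate gave 10 genes for HFD and 7 for MCD, and DESeq2 gave 15 and 18.

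The repeated and single regimens differ in number of doses, time after the last dose and lanes at once. Gc was called as responding more after repeated doses in LFD (log2 difference 2.96, SE 0.49, edgeR adjusted p = 0.00115), HFD (3.85, SE 0.48, adjusted p = 6.16e-07) and MCD mice (3.70, SE 0.53, adjusted p = 3.53e-05). In MCD mice, it stood at 30.9 ± 6.70 and 43.8 ± 10.1 CPM (vehicle and PERC) after a single dose, and at 33.7 ± 6.58 and 625 ± 167 CPM after 5 doses. The other called gene in LFD mice was the folate enzyme gene Aldh1l2 (2.11, SE 0.42, adjusted p = 0.0389), and in MCD mice it was the predicted glutathione transferase copy Gm3776 (adjusted p = 0.00185), chosen after its values were seen. In HFD mice, 16 genes were called higher and 4 lower, among them the protease gene Adamts4 (2.29, SE 0.43), Ucp2 (1.74, SE 0.34) and the elongation factor gene Ell3 (-1.16, SE 0.22). There, the tubular injury list (median 0.654, camera adjusted p = 2.51e-06, and adjusted p = 0.0320 with an estimated correlation), the p53 list (0.416, adjusted p = 2.51e-06, and adjusted p = 0.00533 with an estimated correlation) and the inflammatory list (0.450, adjusted p = 1.92e-06, and adjusted p = 0.0124 with an estimated correlation) passed both ways. These list tests were not rerun without HFD repeated PERC replicate 6, on which the Lcn2 call rested. Havcr1 differences did not pass (3.02, 2.30 and 2.85 in LFD, HFD and MCD mice, with edgeR adjusted p = 0.815, 0.470 and 0.476).

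Counts of such regimen differences moved with the settings. In HFD mice, 20 genes were called, 50 with DESeq2 (40 higher, 10 lower), 97 with lane as a covariate (48 higher, 49 lower) and 6 in a fit to only the 4 groups. The count was 13, 9 and 6 without single PERC replicates 1, 3 and 4, and 7, 8 and 9 without single vehicle replicates 3, 4 and 5; Gc, Adamts4, Ucp2 and Ell3 were called in each of these fits. In LFD mice Gc remained called and Aldh1l2 was not in 16 of 25 fits with 1 library left out (highest adjusted p = 0.210) or with lane as a covariate (adjusted p = 0.0530); without single PERC replicate 3, 1 gene was higher and 2 lower. In MCD mice, the count was 1 without single vehicle replicate 3, 5 without single PERC replicate 5 and 4 with lane as a covariate.

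Among vehicle mice of the single regimen, HFD kidneys differed from LFD kidneys in cell cycle genes and in 9 clock genes, whose list did not pass with an estimated correlation (4 against 5 libraries). Ces1g (chromosome 8, 93302369 to 93337308) was the largest decrease, from 66 ± 28.3 to 4.58 ± 1.11 CPM (log2 -3.82, SE 0.36, edgeR adjusted p = 5.27e-06). Synpr, which codes for the vesicle protein synaptoporin (chromosome 14, 13284780 to 13616340), rose from 0.140 ± 0.0645 to 7.29 ± 3.71 CPM (5.75, SE 0.86, adjusted p = 0.000456). The clock repressor gene Ciart rose by 2.94 (SE 0.35), while the clock activator genes Arntl (-1.54, SE 0.21) and Npas2 (-2.31, SE 0.31) fell. Of 19 clock genes, 6 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 2.25e-05, and adjusted p = 0.0824 with an estimated correlation). Of 35 cell cycle genes, 6 rose and 1 fell (16 and 2 adjusted over the list alone; median 0.612, adjusted p = 3.32e-14, and adjusted p = 0.0197 with an estimated correlation). These included Cdk1 (1.32, SE 0.26) and Tpx2 (1.35, SE 0.28). The cell cycle list lay lower with PERC in HFD mice after a single dose, against these same 4 HFD vehicle libraries, so the results are not independent. Of 7 markers of the acid-base regulating intercalated cells, 1 fell and 6 did not pass (4 fell adjusted over the list alone; median -0.326, adjusted p = 0.000279, and adjusted p = 0.0197 with an estimated correlation). Pck1, the gluconeogenic carboxykinase gene, rose by 2.14 (SE 0.41, adjusted p = 0.00468), and Spp1, the osteopontin gene, fell by 0.60 on the log2 scale (SE 0.11). In all, 234 genes were called (53.4% higher), 375 with DESeq2 and 438 with lane as a covariate. There were 87 higher and 61 lower without HFD vehicle replicate 3, and 81 and 68 without replicate 5. Without LFD vehicle replicate 2 there were 113 higher and 122 lower.

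MCD kidneys of the single regimen (3 against 5 vehicle libraries) had 68 called genes, 31 higher and 37 lower. Synpr (log2 5.27, SE 0.91, edgeR adjusted p = 0.00868), the contactin-associated gene Cntnap5a (2.62, SE 0.37, adjusted p = 0.00158) and the glucuronosyltransferase gene Ugt2b37 (1.72, SE 0.22, adjusted p = 0.000916) rose, and Cdhr2, a brush border cadherin gene, fell (-0.91, SE 0.14, adjusted p = 0.00588). Of 35 cell cycle genes, 2 rose (7 adjusted over the list alone; median 0.495, camera adjusted p = 1.01e-15, and adjusted p = 0.0125 with an estimated correlation). None of 7 intercalated cell markers passed over all genes and 4 fell when adjusted over the list alone (median -0.383, adjusted p = 9.43e-06, and adjusted p = 0.00573 with an estimated correlation). Of 19 clock genes, Ciart and Tef rose and Npas2 fell (6 and 2 adjusted over the list alone; median 0.329, adjusted p = 0.00550, and adjusted p = 0.324 with an estimated correlation). Each lost the call without 1 or more libraries (highest adjusted p = 0.0775, 0.175 and 0.215). NRF2 targets had a median of -0.191, with 0 called and 4 lower when adjusted over the list alone (adjusted p = 0.000163, and adjusted p = 0.0182 with an estimated correlation). Of the 29 named genes called, 6 kept the call whichever library was left out, among them Synpr, Cntnap5a, Ugt2b37 and Cdhr2. The count was 118 with DESeq2, 114 with lane as a covariate and 12 in a fit to only these groups (9 higher, 3 lower). Without MCD vehicle replicates 2, 3 and 5 it was 10 (8 higher, 2 lower), 29 (20 and 9) and 32 (15 and 17). Without LFD vehicle replicates 3, 4 and 5 it was 23 (15 and 8), 26 (17 and 9) and 44 (23 and 21).

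**Figure D4:**
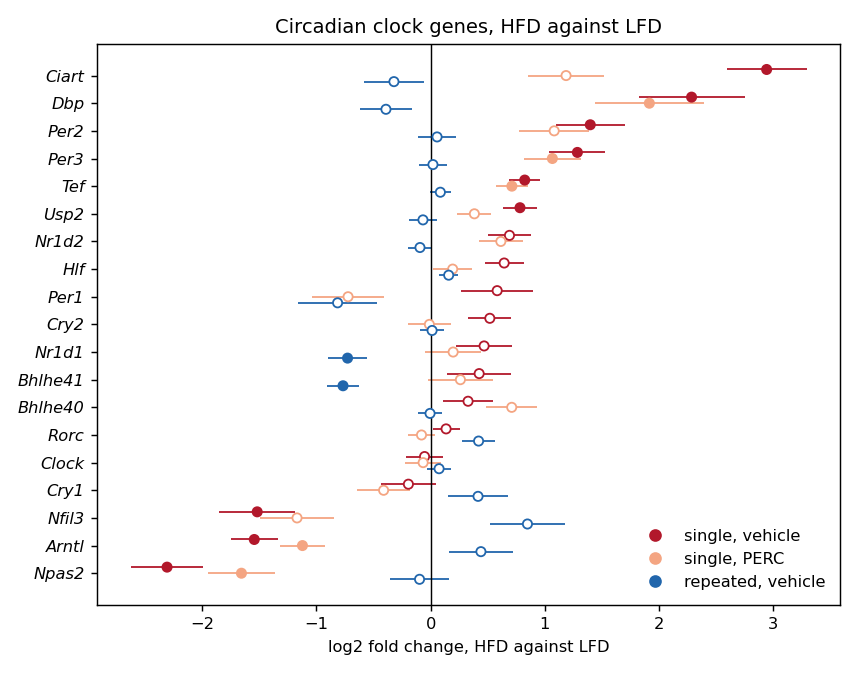
Log2 fold changes of HFD against LFD for 19 circadian clock genes in single and repeated regimens; points are estimates, filled where the adjusted p was under 0.05, and bars are 1 SE. In vehicle mice of the single regimen 9 of 19 genes passed, and in those of the repeated regimen 2 did.

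In vehicle mice of the repeated regimen, HFD kidneys had 970 called genes against LFD kidneys (564 higher, 406 lower; 8 against 7 libraries). Ctxn3, a cortexin gene, rose by a log2 value of 3.56 (SE 0.37, edgeR adjusted p = 8.91e-09), the transporter gene Slco1a1 by 2.15 (SE 0.38) and Pck1 by 1.58 (SE 0.23, adjusted p = 7.03e-06). Cyp2e1, a cytochrome P450 that oxidizes small solvents, rose by 0.77 (SE 0.13, adjusted p = 7.14e-05), from 1475 ± 222 to 2508 ± 177 CPM. Ces1g (-3.60, SE 0.46), the retinol transporter gene Stra6 (-2.32, SE 0.26) and Spp1 (-0.67, SE 0.11) fell. Of 7 intercalated cell markers, 5 fell (6 adjusted over the list alone; median -0.420, camera adjusted p = 3.17e-06, and adjusted p = 0.0162 with an estimated correlation). These included the pendrin gene Slc26a4 (-0.48, SE 0.09) and the proton pump gene Atp6v1g3 (-0.53, SE 0.10). Of 31 glutathione and mercapturate genes, 2 rose and 7 fell (4 and 10 adjusted over the list alone; adjusted p = 0.115). Fat markers moved with the same groups: 6 of 11 adipocyte markers rose (8 adjusted over the list alone; median 1.57, adjusted p = 8.74e-05, and adjusted p = 0.486 with an estimated correlation) and 4 of 5 brown adipocyte markers rose (4 adjusted over the list alone; median 3.82, adjusted p = 0.00231, and adjusted p = 0.486 with an estimated correlation). These included Ucp1, the thermogenic uncoupling protein gene (5.28, SE 1.13). With those markers as a covariate, 394 genes were called, 372 of them among the 970; a fit to only these groups called 1703.

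MCD kidneys of the repeated regimen had 508 called genes against LFD kidneys (308 higher, 200 lower; 7 against 7 vehicle libraries). The chemerin gene Rarres2 rose by a log2 value of 1.77 (SE 0.18, edgeR adjusted p = 6.46e-09), Ctxn3 by 2.89 (SE 0.38) and Slco1a1 by 1.87 (SE 0.38), while Stra6 (-2.03, SE 0.26) and Spp1 (-0.74, SE 0.12) fell. Of 15 macrophage and dendritic cell markers, 5 rose (12 adjusted over the list alone; median 0.473, camera adjusted p = 3.48e-10, and adjusted p = 0.0739 with an estimated correlation). These included the lysozyme gene Lyz2 (0.64, SE 0.14) and Tyrobp (0.55, SE 0.14). Of 28 interferon response genes, 5 rose (10 rose and 1 fell adjusted over the list alone; adjusted p = 7.99e-06, and adjusted p = 0.197 with an estimated correlation). These included Oas2 (0.87, SE 0.18). The macrophage and interferon lists lay lower with PERC in MCD mice after 5 doses, against these same 7 MCD vehicle libraries. High values in that group alone would give both results, so they are not independent. Of 7 intercalated cell markers, 4 fell (6 adjusted over the list alone; median -0.412, adjusted p = 8.15e-08, and adjusted p = 0.00534 with an estimated correlation). Fat markers also moved with the groups, against the same 7 LFD vehicle libraries as for HFD, so this is no separate repeat of the HFD result. Of 11 adipocyte markers, 3 rose (8 adjusted over the list alone, median 1.71, adjusted p = 2.15e-07, and adjusted p = 0.197 with an estimated correlation). Of 5 brown adipocyte markers, 4 rose (adjusted p = 2.86e-05, and adjusted p = 0.197 with an estimated correlation). With those markers as a covariate, 70 genes were higher and 69 lower, and Slco1a1 and Tyrobp did not pass (adjusted p = 0.0596 and 0.125). The count was 327 without LFD vehicle replicate 6 and 897 in a fit to only these groups.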

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

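Of the tests in this part, those on the library labelled LFD repeated PERC replicate 4, on clock genes, on adipocyte markers, on Lcn2 without 1 library and on splits for PERC in single-regimen mice were chosen only after the result was seen; the splits of the other 14 comparisons were planned.

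The library labelled LFD repeated PERC replicate 4 stood with the vehicle libraries for PERC-responsive genes. Its PERC score was 0.0827, inside the range of the 7 LFD vehicle libraries (0.0189 to 0.144) and below the other 8 PERC libraries (0.350 to 0.928). An exchange with a vehicle library of its group was argued against, since 0 of the 7 had a score in the PERC range, and so was depth, since the score was 0.0870 after thinning to the median depth of the other 8. A vehicle kidney under a PERC label, or an animal that showed no response, remains open, and these cannot be separated with the data used here. Labels give 9 PERC and 7 vehicle libraries where the series description gives 8 and 8.

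Clock genes differed between HFD and LFD kidneys of the single regimen, with 9 of 19 called in vehicle mice. Lane was argued against, as 11 were called with lane as a covariate. A diet effect of equal size in both regimens was also argued against, since the mixed set test of the difference between regimens gave a p value of 0.000539 (fry, a rotation set test, over the 72 libraries). In MCD vehicle mice 3 of 19 were called (5 with lane as a covariate), with the signs of HFD mice, but both comparisons share the LFD libraries. Another time of collection or feeding for the LFD mice could give such a pattern, and 16 of 19 genes had the same sign in PERC and vehicle mice, but a diet effect on the clock would do the same, so these cannot be told apart because no collection time was given.

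Adipocyte markers differed between groups of the repeated regimen. PERC in LFD mice, the diet comparisons and the differences from the LFD effect all hold the same 7 LFD vehicle libraries, so their marker shifts are not independent. Within groups, the median pairwise correlation of the markers was 0.546, and 0 of 9969 random lists of like size and level reached it. Varying amounts of fat tissue in the pieces of kidney would give this, but so would any set of genes regulated together. This correlation does not bear on the cause of the difference between groups. Library depth stays open as a part of it: over 47 libraries, the correlation with log2 depth within groups was r = -0.291 (permutation p = 0.0473), and -0.0126 without the 2 farthest libraries. The rank correlation over the same 47 libraries was -0.158 (Spearman, permutation p = 0.29). A change of fat tissue with diet or PERC was not tested and may also play a part, and fits with the markers as a covariate called 669 genes for PERC in LFD repeated mice and 394 for HFD against LFD.

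Other groupings of the same libraries were tried for each count, the real one included. Where under 5% of them gave as many calls, that share argued against chance for that count, with no correction for the number of counts tried. For PERC in single-regimen mice, 2 of 100 splits gave at least 107 calls on LFD (highest other 1225), 3 of 100 at least 1 on HFD (highest other 2) and 1 of 35 at least 4 on MCD (highest other 0). For PERC in repeated-regimen mice, 1 of 100 did so for 1010 on LFD (highest other 534), for 1342 on HFD (697) and for 745 on MCD (607). For diet, 1 of 100 reached 234 for HFD single (highest other 77), 2 of 56 reached 68 for MCD single (4692), and 1 of 100 reached 970 for HFD repeated (555) and 508 for MCD repeated (39). The splits with 1225 and 4692 calls followed lane and gave several times the real count, which points to a structure of the samples. Splits that ignore lane therefore do not exclude chance for the counts of 107 and 68. With lane as a covariate, the real counts were 286 and 114. The share for PERC in HFD single mice rests on 1 gene and does not exclude chance either. There, 3 of 9 fits with 1 library left out called 0 genes. For the count of 4 on MCD, the splits also ignored lane, and 1 of 35 is the smallest share they can give. Of 7 fits for MCD with 1 library left out, 3 called 0 genes, so chance is not excluded for that count either. For the repeated minus single difference, 1 of 100 reached 20 in HFD mice (highest other 2) and 4 of 100 reached 2 in MCD mice (24). These splits exchanged regimen labels within PERC and within vehicle libraries, which mixed regimens and lanes. Any difference between regimens shared by PERC and vehicle libraries then entered the spread. They therefore cannot decide on chance for a difference of PERC effects.

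Chance cannot be excluded for 2 further counts, whose splits exchanged diet or regimen labels in the same way and carry the same limit. For the repeated-regimen difference between HFD and LFD effects, 6 of 100 splits gave at least the 2 calls (highest other 2825), and for the regimen difference in LFD mice 13 of 100 gave at least 2 (highest other 3529). For counts of 0 in the differences from LFD, all 100 splits give as many whatever the data, so they decide nothing (highest others 225 for HFD single, 4268 for MCD single and 336 for MCD repeated). Splits with such counts point to a structure of the samples.

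Libraries far from the others of their group were sought in 110 combinations of 10 genes and 11 groups (the group of 3 libraries was left out), where chance gives about 1 in 20 combinations, and 10 were found, of which 6 are given. Lcn2 was 35.23 CPM in HFD repeated PERC replicate 6 (others 2.187 to 7.23), and without that library Lcn2 did not pass for PERC (adjusted p = 0.0695). Acot1 was 29.81 CPM in LFD repeated vehicle replicate 7 (others 39.43 to 47.91). Havcr1 was 1.714 CPM in MCD repeated PERC replicate 6 (others 10.32 to 48.44) and 1.109 CPM in MCD repeated vehicle replicate 8 (others 1.42 to 1.678), where Cdkn1a was 2.835 CPM (others 4.701 to 5.36). In MCD single PERC replicate 1, Cyp4a10 was 1444 CPM (others 826.9 to 862.7).

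By direct test, effects that differed between diets were those of Sntg2 (log2 1.5423) and Angptl4 (1.5290) in repeated HFD against LFD mice. With the adipocyte covariate, the call of Angptl4 was lost, although its difference was still 1.543 (SE 0.3046, edgeR adjusted p = 0.0599). Effects that differed between regimens were those of Gc in LFD (2.9581), HFD (3.8532) and MCD mice (3.6963), Aldh1l2 in LFD (2.1144) and HFD mice (1.8761), and Gm3776 in MCD mice (adjusted p = 0.00185). In HFD mice, they were also those of Adamts4 (2.2869), Ell3 (-1.1596), Sucnr1 (-1.0267), Crispld2 (0.8556), Ucp2 (1.7440), Kif23 (1.3464), Pdk4 (3.1502), Sgk1 (2.0159), Tln2 (-0.6726), Osmr (1.1826), Psat1 (1.0427) and Cxcl1 (1.8862). Of these 14 calls in HFD mice, those of Gc, Adamts4, Ell3 and Ucp2 were kept whichever of 9 libraries was left out. The other 10 were lost in at least 1 of the 9 fits, that of Aldh1l2 in 8 and that of Cxcl1 in 9. The call of Cxcl1 was also lost with the adipocyte covariate, although its difference was still 1.8643 (SE 0.4435, edgeR adjusted p = 0.0521). In LFD mice, the call of Aldh1l2 was lost in 16 of 25 fits. Median differences of 3 lists in HFD mice were 0.654 for tubular injury, 0.416 for p53 targets and 0.450 for inflammatory genes. These lists were not rerun without HFD repeated PERC replicate 6.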

How the results depend on the processing

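In this part, fits with the adipocyte covariate, those of PERC in HFD and MCD repeated mice without 1 library, and those with lane or DESeq2 that left out the doubted LFD PERC library, were chosen only after the result was seen. Libraries left out 1 at a time were those of the single regimen and of LFD repeated mice. No call of a named gene changed sign with DESeq2, RLE scaling, lane as a covariate or, in contrasts that hold such libraries, without any 1 of them. The balance of higher and lower calls did turn in some fits. With lane as a covariate it turned for PERC in LFD single (47.6% higher), PERC in MCD repeated (364 higher, 369 lower) and repeated minus single in HFD (48 and 49). For MCD against LFD single vehicle (31 higher, 37 lower), it turned in the fit to only these groups (9 and 3) and without MCD vehicle replicates 2 (8 and 2) or 3 (20 and 9) or LFD vehicle replicates 3 (15 and 8), 4 (17 and 9) or 5 (23 and 21). It also turned for HFD against LFD single without LFD vehicle replicate 2 (113 and 122), and for PERC in HFD single without vehicle replicate 1 (1 and 2) and in MCD single without vehicle replicate 3 (0 and 1). For repeated minus single in LFD it turned without single PERC replicate 3 (1 and 2). Of 17 counts, 16 stayed within 1.5 times with RLE scaling, 16 with no filter on low counts and 15 with low-depth libraries kept in. The minimum of 5000000 counts removed no library, so it says nothing, and the repeated regimen has no low-depth library. Where counts moved, the cause was not tested. No paired analysis was possible because replicate numbers were given in accession order and pair nothing.

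With lane as a covariate, counts were 286 for PERC in LFD single, 17 in MCD single, 1 and 1 for the HFD and MCD minus LFD effects of a single dose, 3 for MCD minus LFD repeated, and 1, 97 and 4 for repeated minus single in LFD, HFD and MCD mice. With low-depth libraries kept in, PERC gave 2 in HFD single and 13 in MCD single. DESeq2 gave 222, 13 and 43 for PERC in LFD, HFD and MCD single, 3 and 2 for the single-dose differences, 6 and 2 for the repeated ones, and 50 for repeated minus single in HFD. RLE gave 1 for MCD minus LFD repeated, and no filter gave 1 for repeated minus single in LFD.

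In fits to only the groups compared, which have fewer libraries to estimate spread, counts were 8 for PERC in LFD single, 363 in LFD repeated, and 0 and 6 for repeated minus single in LFD and HFD; for the 0, edgeR gave 2 over all groups. Without the doubted library, lane as a covariate gave 1903 for PERC in LFD repeated and 10 and 7 for the HFD and MCD differences, and DESeq2 gave 1985, 15 and 18, and 11 for repeated minus single in LFD, where it adjusted over 1432 genes against 20636 with all libraries (2 calls). The adipocyte covariate gave 49, 4 and 7 for PERC in LFD, HFD and MCD single, 669 in LFD repeated and 1 for HFD minus LFD repeated. Of 578 list tests, 193 passed, 195 with lane as a covariate and 22 with an estimated correlation.

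With each of those libraries left out in turn, lowest and highest counts for PERC were 19 and 285 in LFD single, 0 and 3 in HFD single, 0 and 5 in MCD single, and 640 and 1798 in LFD repeated. For differences from LFD they were 0 and 3 (HFD single), 0 and 2 (MCD single), and, over the 16 LFD libraries only, 2 and 5 (HFD repeated) and 0 and 3 (MCD repeated). For repeated minus single they were 1 and 3 over all 25 libraries in LFD, and, over single-regimen libraries only, 6 and 18 in HFD and 1 and 5 in MCD mice. PERC in HFD and MCD repeated mice was run only without 3 libraries far from their group, with 928 calls without HFD PERC replicate 6, and 579 and 612 without MCD PERC replicate 6 and vehicle replicate 8. Named genes that were called were tested 3626 times without 1 single-regimen or LFD repeated library, and passed 2922 times and not 704 times. With lane as a covariate, of 2589 values of named genes, called or not, 2472 kept their side of the threshold, 12 no longer passed and the rest newly passed.

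Calls between diets in vehicle mice, as a percentage of the genes tested, were 1.639 and 0.4762 for HFD and MCD single, and 6.637 and 3.476 for HFD and MCD repeated. With lane as a covariate they were 3.067 and 0.7983 in the single regimen, and with DESeq2 2.46 and 0.7941. In fits to only the groups compared they were 0.08707 for MCD single, 12.09 for HFD repeated and 6.366 for MCD repeated. The adipocyte covariate gave 2.696 and 0.9511 for HFD and MCD repeated. With 1 library left out, lowest and highest percentages were 1.042 and 1.647 (HFD single), 0.06943 and 0.4696 (MCD single) and, over the 7 LFD vehicle libraries only, 4.689 and 6.903 (HFD repeated) and 2.229 and 3.307 (MCD repeated).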

Other observations

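All 38 lists were planned, and no test in this part was chosen after the result was seen. In LFD mice after a single dose, extracellular matrix genes had a median log2 value of -0.210, with 1 of 28 lower, Mmp2 (-0.71, SE 0.17, edgeR adjusted p = 0.0383, and 0.259 at most with 1 library left out; camera adjusted p = 8.44e-05, and adjusted p = 0.339 with an estimated correlation). In HFD mice after 5 doses, the neutrophil genes S100a8 (2.22, SE 0.49, edgeR adjusted p = 0.00184) and S100a9 (1.73, SE 0.48, adjusted p = 0.0144) rose. Neither was checked without PERC replicate 6, on which the Lcn2 call of that comparison rested. In LFD mice after a single dose, unfolded protein response genes had a median of -0.185, with 0 called over all genes and 3 lower when adjusted over the list alone (camera adjusted p = 0.000470, and adjusted p = 0.349 with an estimated correlation).

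Among cell type lists, podocyte markers (lowest camera adjusted p = 0.0532), endothelial markers (0.133), stromal markers (0.0788) and hepatocyte markers (0.199) passed in none of the 17 comparisons. Neutrophil, erythroid, adrenal cortex and skeletal muscle lists had under 5 tested members and were not tested as lists.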
